A study of Homo sapiens with 15 samples.

How the data were processed

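Total RNA of A549 cells was measured on 15 Affymetrix human hgu133a arrays, 3 each for untreated cells at 0 h and 24 h and cells with IL-13 for 4 h, 12 h and 24 h. The values are signal intensity per probe set as deposited, on a linear scale, 22283 probe sets per array with no missing values. How the authors computed them is not given in the sources used here; the mean of each array after trimming 2% at each end is 150, as the MAS 5.0 scaling of Affymetrix gives.

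All choices of groups, tests, filters, gene lists and the rule for named genes were made before the data were examined, except scaling on the median of the tested genes, the tests and lists named as later ones in the closing section, and genes said in the text to be named after their values were seen. Negative values would have been set to 0, a pseudocount of 20 (the 25th percentile of all values) was added and log2 taken. Fold changes are therefore on the log2(signal + pseudocount) scale, which understates changes of dim genes. Array medians differed by up to 0.269 log2, over the tolerance of 0.1, so the arrays were quantile normalized. Of the probe sets, 68 are array controls, 19065 carry a single gene symbol, 1043 several and 2107 none; of the symbols 19053 were matched through the Entrez identifier and 0 changed. Each of 11963 genes was represented by the probe set with the highest mean, with sets of the cross-hybridizing _x_at kind used only where a gene had no other; 8 named genes, CISH and MPPE1 among them, rest on such sets. Genes with a mean log2 signal over 6.33, the median of the probe sets that are not controls (50th percentile), were tested, 6884 in all. CCL26, one of the genes set in advance, has no probe set with that symbol alone.

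Groups were compared with limma 3.58.1 in R 4.3.3: a linear model with 1 mean per group over all 15 arrays (10 residual degrees of freedom), empirical Bayes moderation with a variance trend, two-sided tests and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. The 7 comparisons were IL-13 24 h with control 24 h, control 24 h with control 0 h, IL-13 at each time with control 0 h, and 12 h with 4 h and 24 h with 12 h of IL-13. A set of 20 gene lists was tested with camera (limma) at its preset correlation of 0.01 and again with a correlation estimated per list; 1 list with under 5 tested genes was not tested. Counts of list members are by the adjustment over all genes unless said to be adjusted over the list alone. Precision is limited by 3 arrays per group. The same steps were tested on simulated data, with changes placed in genes of IL-13 24 h against control 24 h. Of these, 74.2% of 62 genes changed 1.5-fold, 98.5% of 66 changed 2-fold and 100% of 61 changed 3-fold were recovered. Of 183 calls, 8 (4.37%) were false. The DNA replication list was also shifted downward, and its genes were not counted as false calls. Noise was drawn independently for each gene, so the simulation holds no genes that vary together and no deviating array.

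Apart from genes said to be named after their values were seen, genes were named from sets fixed by a rule, of which the text describes most of the largest changes and some of the list members: in the first 4 comparisons the 12 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap, in the other 3 the 5 largest of each; where fewer than 5 genes passed, the 5 with the smallest p; up to 4 members with the smallest p of each list with a camera adjusted p under 0.05; and IL13RA1, IL13RA2, IL4R, STAT6, SOCS1, CISH, CCL26 and MUC5AC in every comparison, with the genes of the 24 h comparison followed through time. Alternatives tried were the deposited scaling, median scaling, tested-gene median scaling, pseudocounts of 1 and 62 (the median), no filter, a filter at the 75th percentile, the mean of a gene's probe sets, every probe set as its own test, only the compared groups in the model, no variance trend, array weights, the replicate letter as a block and leaving out each array. Probe sets with several symbols or none were left out of the gene tests, since they name no single gene. No scanner files and no detection calls were used here. Some results that name items withheld for evaluation are not reported here.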

Results

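A549 cells, given in the labels as a human bronchial cell line and known as a lung adenocarcinoma epithelial line, were profiled on Affymetrix human arrays in 5 groups of 3 arrays. The groups were untreated at 0 h and 24 h, and treated with IL-13 for 4 h, 12 h and 24 h. The median signal per array ran from 56.8 to 72.5. By group it was 59.1 ± 1.80 in control 0 h, 69.5 ± 3.10 in control 24 h, 61.6 ± 3.60, 62.4 ± 3.24 and 59.3 ± 4.44 after 4 h, 12 h and 24 h of IL-13 (mean ± SD, n = 3 arrays). The 3'/5' signal ratio of the array's control probe sets, a measure of RNA integrity, ran from 0.844 to 0.918 for GAPDH and from 0.930 to 1.24 for beta-actin. The beta-actin ratio differed between the times: it was 1.001 ± 0.065 in control 0 h and 1.171 ± 0.066 in control 24 h, and 1.025 ± 0.078, 1.083 ± 0.049 and 1.180 ± 0.081 after 4 h, 12 h and 24 h of IL-13. Arrays of the same group correlated at 0.972 to 0.979, and 6884 genes were tested. No untreated arrays at 4 h or 12 h are labelled, so at those times a difference from 0 h holds both IL-13 and time in culture. At 24 h the control is matched in time. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Gene values are log2 differences ± SE with 3 arrays per group.

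The first question was what 24 h of IL-13 changed against untreated cells of the same time in culture. RGS2, a regulator of G protein signalling, rose by 1.67 ± 0.16 (3.17-fold, adjusted p = 2.0e-05). The mean deposited signal of RGS2 was 179.8 at 0 h, 119 in the 24 h control and 385.7 after 24 h of IL-13. Untreated cells thus stood lower at 24 h than at 0 h for this gene. The lysosomal protease cathepsin L (CTSL) rose by 1.41 ± 0.12 (2.66-fold, adjusted p = 6.1e-06). Complement component C3 rose by 1.39 ± 0.26 (2.62-fold, adjusted p = 0.00382), and CISH, a SOCS family inhibitor induced by STAT proteins, by 1.03 ± 0.14 (2.05-fold, adjusted p = 0.000381). The matrix proteoglycan VCAN fell by 1.12 ± 0.13 (2.17-fold, adjusted p = 5.6e-05), with all 4 of its other probe sets lower as well. Its mean deposited signal was 274.2 at 0 h, 498.1 in the 24 h control and 226.1 after 24 h of IL-13, so untreated cells had risen.

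Other large rises were those of the splicing regulator MBNL2 (1.30 ± 0.16), ENC1 (1.27 ± 0.22), OLFML2A (1.27 ± 0.18), the homeobox factor MSX1 (1.16 ± 0.13), hexokinase HK1 (1.15 ± 0.13, 2.22-fold) and LRFN4 (1.09 ± 0.19). MPPE1 rose 2.84-fold (adjusted p = 0.00155) on its brightest probe set and stood 0.26 and 0.76 higher on the other pair. The deubiquitinase JOSD1 (1.32 ± 0.38, adjusted p = 0.0420) lost its call in 12 of 18 other settings (range 0.90 to 1.69), any of the 6 arrays left out among them. ATF6, a sensor of endoplasmic reticulum stress (1.14 ± 0.27), lost its call with no filter, with the mean of probe sets, and without control 24 h array b or IL-13 24 h array b or c (range 0.51 to 1.44). It stood at -0.13 on its other probe set. For LRFN4, MPPE1, JOSD1 and ATF6 the untreated cells stood lower at 24 h than at 0 h. Mean deposited signals at 0 h, in the 24 h control and after 24 h of IL-13 were 108.5, 28.35 and 72.51 for LRFN4. For MPPE1 they were 82.58, 29.46 and 104.6, for JOSD1 121, 43.36 and 124.7, and for ATF6 120.2, 59.76 and 133.5. Among the falls, FLRT2 fell by 1.03 ± 0.18, the insulin receptor substrate IRS2 by 0.95 ± 0.15 (adjusted p = 0.00102, other probe set -0.87) and the IGF1 receptor IGF1R by 1.01 ± 0.24 (other probe sets -0.68 and 0.08). IGF1R lost its call with no filter and without control 24 h or IL-13 24 h array c (range -1.17 to -0.53). The calcium channel gene CACNA1I (-1.35 ± 0.35, other probe sets -0.15 and 0.11) lost its call in 6 of 17 other settings (range -1.50 to -0.19), including without control 24 h array a or c and IL-13 24 h array a or b. GGA2 (-0.98 ± 0.20) had the same sign on 2 of 7 other probe sets and lost its call with the mean of probe sets. FLRT2 and IRS2 stood higher in untreated cells at 24 h than at 0 h. Mean deposited signals at 0 h, in the 24 h control and after 24 h of IL-13 were 79.29, 154.7 and 59.81 for FLRT2. For IRS2 they were 283.6, 400 and 203.9.

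**Figure D1:**
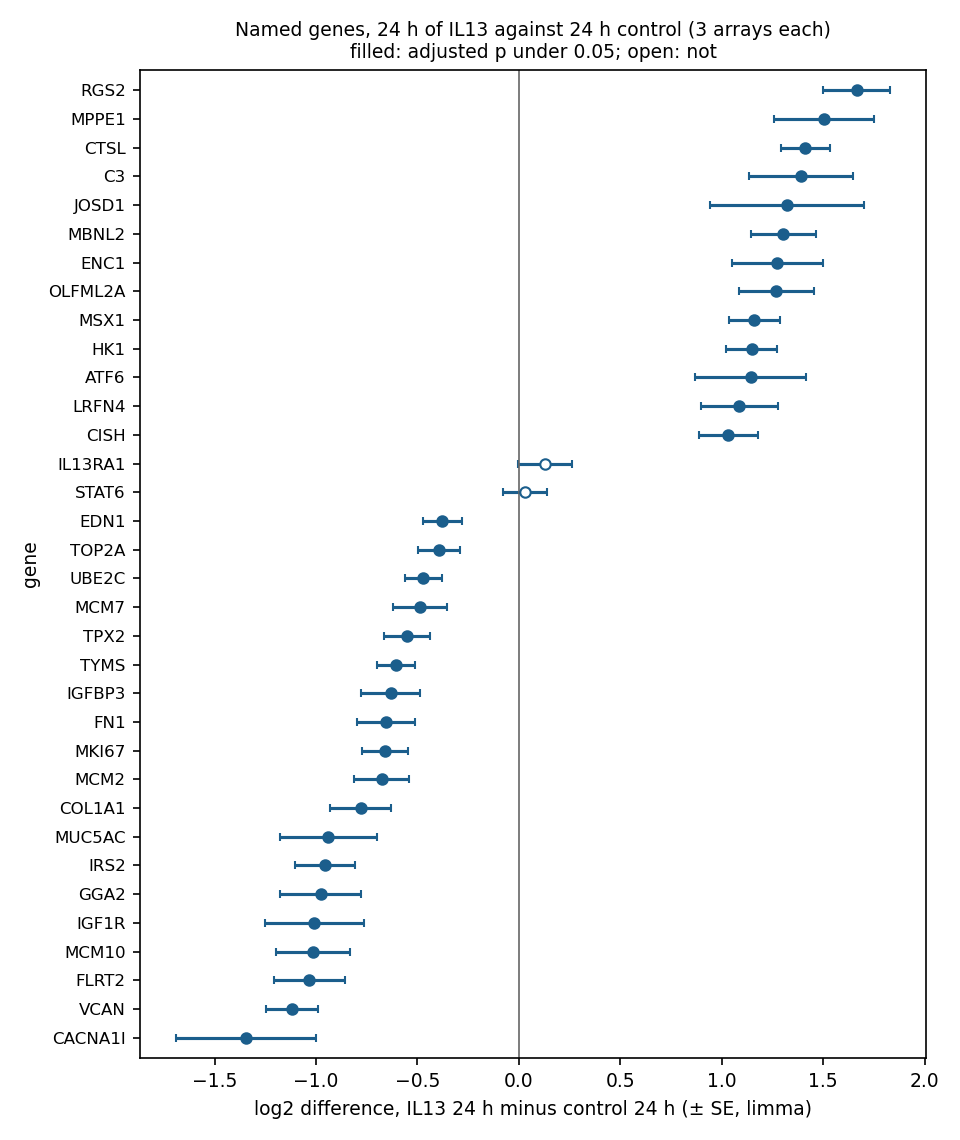
Log2 difference ± SE of the named genes between 24 h of IL-13 and 24 h control, 3 arrays per group. Filled circles mark an adjusted p under 0.05.

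Of the mitotic list, 7 of 32 tested genes fell (16 when adjusted over the list alone). Its mean difference was -0.27 (camera adjusted p = 1.9e-08, and adjusted p = 0.372 with an estimated correlation). The proliferation marker MKI67 fell by 0.66 ± 0.11 (adjusted p = 0.00212) and the spindle factor TPX2 by 0.55 ± 0.11 (adjusted p = 0.00770). Of the DNA replication list, 5 of 28 fell (1 rose and 6 fell when adjusted over the list alone, camera adjusted p = 0.0109, and adjusted p = 0.701 with an estimated correlation). Among them were the replication initiation factor MCM10 (-1.02 ± 0.18), the helicase subunit MCM2 (-0.68 ± 0.14) and thymidylate synthase TYMS (-0.60 ± 0.09). Of the growth factor and matrix list, 4 of 30 fell (1 rose and 5 fell when adjusted over the list alone, camera adjusted p = 0.00195, and adjusted p = 0.372 with an estimated correlation). These were COL1A1 (-0.78 ± 0.15), FN1 (-0.66 ± 0.14, 4 of 5 other probe sets lower, 1 at 0.16), IGFBP3 (-0.63 ± 0.15) and EDN1 (-0.38 ± 0.10). With median scaling TPX2, TYMS, FN1, IGFBP3 and EDN1 lost their calls, and FN1, IGFBP3 and EDN1 also without IL-13 24 h array c. EDN1 lost its call in 7 of 19 other settings. The mean deposited signal of FN1 was 1013 at 0 h, 1582 in the 24 h control and 1117 after 24 h of IL-13. The mitotic list kept its call with median scaling, with a mean of -0.07. The replication list lost its call with the deposited, median (mean 0.0028) and tested-gene median scaling, and without control 24 h array b (mean -0.07) or IL-13 24 h array a (-0.11) or b (-0.15). COL1A1 and TYMS also lost their calls with the mean of probe sets. Markers of leukocytes, fibroblasts and endothelium gave 1 fall, COL1A1, among 6 tested genes (camera adjusted p = 0.677).

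Of 35 genes set in advance as known targets of IL-13 in airway epithelium, 28 had a probe set with a single symbol. Of these, 7 were bright enough to test. CISH and the transglutaminase TGM2 (0.52 ± 0.10) rose and the gel-forming mucin MUC5AC fell by 0.94 ± 0.24 (adjusted p = 0.0246). The mean deposited signal of MUC5AC was 98.38 at 0 h, 172.8 in the 24 h control and 75.56 after 24 h of IL-13. The list as a whole did not pass (camera adjusted p = 0.801). MUC5AC lost its call with no filter and without control 24 h array a or c or IL-13 24 h array a or c, and its difference lay between -1.12 and -0.71 over all settings. Its 3 other probe sets, all dimmer than the tested genes, ran from -0.13 to 0.57. The one at 0.57 moved the other way with an unadjusted p of 0.00258, beside 0.00245 for the probe set that fell, so the direction for this gene depended on the probe set. IL13RA1, the signalling receptor chain, stood at 0.13 ± 0.13 (adjusted p = 0.584, other probe sets -0.01 to 0.20). STAT6, its transcription factor, stood at 0.03 ± 0.11 (adjusted p = 0.898, other probe set 0.62). The decoy receptor IL13RA2 (-0.20 ± 0.26), IL4R (-0.07 ± 0.35) and SOCS1 (0.39 ± 0.22, other probe sets -0.13 to 0.16) were too dim for the main test and did not pass with no filter, here or in the other 6 comparisons. The CISH and MPPE1 probe sets are of a kind that can cross-hybridize.

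In all, limma called 482 of 6884 genes, 271 higher and 211 lower (56.2% higher), 27 of them by at least 2-fold (21 higher, 6 lower). The split depended on scaling. Median scaling took the median difference of all tested genes from 0.0016 to 0.138 log2, and 952 genes were higher and 66 lower (93.5% higher). With scaling on the median of the tested genes, 443 were higher and 147 lower (75.1%). The count was 194 without IL-13 24 h array c, 282 without IL-13 24 h array a, 253 without control 24 h array a, 225 without control 24 h array c and 243 with only these groups in the model.

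The next question was what 24 h in culture changed without IL-13. The largest rise among the named genes was that of the desaturase SCD5 (1.45 ± 0.36, adjusted p = 0.0302), which lost its call in 7 of 19 other settings (range 1.21 to 1.67). PTGS2, the inducible cyclooxygenase, rose by 1.21 ± 0.17 (2.32-fold, adjusted p = 0.000806) and PLA2G4A, which releases arachidonic acid, by 0.83 ± 0.14. The vitamin D 24-hydroxylase CYP24A1 rose by 0.86 ± 0.12 and the retinaldehyde reductase DHRS3 by 0.84 ± 0.17 (call lost in 4 of 19 other settings, only these groups among them). RARRES1 rose by 0.89 ± 0.16, VCAN by 0.89 ± 0.13, DDIT4, an inhibitor of mTORC1 signalling, by 0.88 ± 0.13 and ID1 by 0.82 ± 0.10. The zinc finger gene ZBTB20 rose by 0.93 ± 0.13, MEFV by 1.06 ± 0.23 (call lost in 4 of 19 other settings) and APOH by 0.86 ± 0.21 (call lost in 6 of 18). The transcription factor USF2 fell by 1.61 ± 0.18 (3.05-fold, adjusted p = 0.000237) and LRFN4 by 1.54 ± 0.19. The chemokine CCL2 fell by 1.20 ± 0.21 and BCL2A1, an apoptosis inhibitor, by 1.16 ± 0.18. MPPE1 fell by 1.21 ± 0.25 (other probe sets -0.14 and 0.25, call lost in 3 of 17 other settings), ATF6 by 1.01 ± 0.27 (call lost in 13 of 18) and SH3BGRL3 by 0.96 ± 0.25 (call lost in 8 of 19).

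Of the NRF2 and xenobiotic list, 5 of 25 genes rose (8 rose and 1 fell when adjusted over the list alone, camera adjusted p = 0.000150, and adjusted p = 0.142 with an estimated correlation). The 4 with the smallest p were CYP24A1, the transporter ABCC1 (0.54 ± 0.10), the glutathione peroxidase GPX2 (0.47 ± 0.10) and the aldo-keto reductase AKR1C1 (0.74 ± 0.16). ABCC1, GPX2 and AKR1C1 lost their calls with median scaling, and GPX2 and AKR1C1 also without control 0 h array b or control 24 h array c. The list's call was lost with the values scaled as deposited and with median or tested-gene median scaling, and with median scaling its mean turned to -0.03. The list of known IL-13 targets stood higher by 0.28 on average without IL-13 and did not pass (camera adjusted p = 0.0801, and adjusted p = 0.287 with an estimated correlation). None of its 7 tested genes passed, and 2 rose when adjusted over the list alone. CISH stood at 0.26 ± 0.14 (adjusted p = 0.344) and MUC5AC at 0.65 ± 0.24 (adjusted p = 0.135, other probe sets -0.32 to 0.08). IL13RA1 stood at 0.07 ± 0.13 (-0.13 with median scaling) and STAT6 at -0.08 ± 0.11. Limma called 249 genes, 119 higher and 130 lower, 10 of them by at least 2-fold. Median scaling gave 51 higher and 826 lower with the median gene at -0.15, and tested-gene median scaling 110 higher and 231 lower. The count was 66 without control 24 h array c, 73 without control 0 h array b, 115 without control 0 h array c, 141 without control 0 h array a, 144 without control 24 h array a and 155 with no filter.

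How early the cells responded was asked by setting 4 h of IL-13 against untreated cells at 0 h. After 4 h CISH had risen by 1.44 ± 0.14 (2.71-fold, adjusted p = 2.0e-05), more than any other gene called there, and genes of the ATF4 and immediate-early lists had fallen. TRIB3, a pseudokinase induced by ATF4, fell by 1.83 ± 0.15 (3.57-fold, adjusted p = 2.6e-06), and CHAC1, a glutathione-degrading enzyme induced by ATF4, by 1.44 ± 0.21 (adjusted p = 0.00103). The chemokine CXCL2 fell by 1.44 ± 0.14 (adjusted p = 1.5e-05), the growth-responsive matrix protein CCN1 by 1.004 ± 0.170 and TSC22D3, a glucocorticoid-induced gene, by 0.997 ± 0.119. MSX1 (0.87 ± 0.13), MMD (0.82 ± 0.11), CYP1B1 (0.88 ± 0.13), TGM2 (0.70 ± 0.10, other probe sets -0.10 to 0.68), BATF3 (0.68 ± 0.13) and HK1 (0.64 ± 0.13) rose. Other rises were those of HSPA2 (0.75 ± 0.15, call lost in 3 of 19 other settings), MAP3K14 (0.61 ± 0.12, call lost in 5 of 19), TLE4 (0.67 ± 0.14, call lost in 7 of 17) and BCL6 (0.68 ± 0.16, call lost in 12 of 18). NAV2 fell by 0.96 ± 0.13, BIRC2 by 0.91 ± 0.14 and CCSER2 by 0.91 ± 0.19 (other probe set 0.06, call lost in 6 of 18). HK1 lost its call without control 0 h array a or b or IL-13 4 h array c (range 0.56 to 0.69), and BATF3 without control 0 h array b.

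Of the unfolded protein and ATF4 list, 4 of 31 genes fell (15 when adjusted over the list alone). Its mean was -0.33 (camera adjusted p = 1.1e-11, and adjusted p = 0.00783 with an estimated correlation). Besides TRIB3 and CHAC1 the falls were the folate enzyme MTHFD2 (-0.66 ± 0.09) and DDIT4 (-0.60 ± 0.13, call lost in 7 of 19 other settings). Of the immediate-early list, 1 of 18 rose and 5 fell (1 and 10 when adjusted over the list alone, camera adjusted p = 3.8e-09, and adjusted p = 0.00274 with an estimated correlation), including CCN1 and IER3 (-0.52 ± 0.10, call lost without control 0 h array b or IL-13 4 h array a). With only these groups both lists kept the camera call and lost it with an estimated correlation, as the ATF4 list did with median scaling. Of the known targets of IL-13, 2 of 7 rose, CISH and TGM2 (3 rose and 1 fell when adjusted over the list alone, camera adjusted p = 0.00476, and adjusted p = 0.0723 with an estimated correlation). The list lost its call with no filter, which brought 28 members into the test, and TGM2 lost its call with the mean of probe sets. The mean of this list was 0.29, beside 0.28 in untreated cells at 24 h against 0 h.

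In 6 further lists the camera test passed at 4 h and was lost with an estimated correlation. Of the inflammatory list 1 of 15 fell, CXCL2, and 5 when adjusted over the list alone (camera adjusted p = 0.00357, and adjusted p = 0.0776 with an estimated correlation). CXCL1 stood at -0.75 ± 0.19 (adjusted p = 0.0659). Of the growth factor and matrix list 2 of 30 fell, CCN1 and the EGF receptor ligand EREG (-0.87 ± 0.12), and 1 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.00765, and adjusted p = 0.220 with an estimated correlation). Of the circadian list 1 of 8 fell, BHLHE40 (-0.65 ± 0.10), and 2 when adjusted over the list alone (camera adjusted p = 0.0193, and adjusted p = 0.0895 with an estimated correlation). Of the cholesterol list 1 of 22 rose, the sterol sensor INSIG1 (0.61 ± 0.15, call lost in 13 of 18 other settings; camera adjusted p = 0.0203, and adjusted p = 0.220 with an estimated correlation). Of the NRF2 and xenobiotic list 1 of 25 rose, CYP1B1 (camera adjusted p = 0.0353, and adjusted p = 0.220 with an estimated correlation). The DNA replication list stood higher by 0.14 on average (camera adjusted p = 0.00171, and adjusted p = 0.305 with an estimated correlation). No single gene of it passed, over all genes or when adjusted over the list alone, and PCNA stood at 0.64 ± 0.20 (adjusted p = 0.167). The cholesterol and NRF2 lists lost their calls with the filter at the 75th percentile and the mean of probe sets, the inflammatory list with the mean of probe sets, the circadian list with no filter and the growth factor list without IL-13 4 h array a.

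Limma called 84 genes at 4 h, 24 higher and 60 lower, 5 of them by at least 2-fold (1 higher, 4 lower). The count was 35 without control 0 h array b, 38 without control 0 h array a, 37 without IL-13 4 h array c and 49 without IL-13 4 h array a. Without an untreated 4 h group, none of these differences can be assigned to IL-13 rather than to time. IL13RA1 (-0.02 ± 0.13), STAT6 (0.26 ± 0.11, other probe set -0.95) and MUC5AC (-0.09 ± 0.24) did not pass.

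At 12 h of IL-13, again against 0 h, the question was which changes were present between the early and late times. CISH stood 1.29 ± 0.14 higher (2.44-fold, adjusted p = 6.0e-05), HK1 1.11 ± 0.13 (2.16-fold), OLFML2A 1.01 ± 0.18 and CTSL 0.93 ± 0.12. HSPA2, a heat shock protein of the HSP70 family, stood 0.94 ± 0.15 higher, INSIG1 0.90 ± 0.15 and MMD 0.87 ± 0.11. TRIB3 fell by 2.03 ± 0.15 (4.10-fold, adjusted p = 4.7e-07), CHAC1 by 1.40 ± 0.21, CXCL2 by 1.38 ± 0.14, CCN1 by 1.43 ± 0.17, EREG by 1.22 ± 0.12, CDC42EP1 by 1.22 ± 0.20, NPIPA1 by 2.01 ± 0.28 and RUSC2 by 1.24 ± 0.27 (call lost without IL-13 12 h array a or c). TBC1D4 rose by 0.92 ± 0.14, and ENC1 by 0.87 ± 0.22 (call lost in 8 of 19 other settings). C3 rose by 1.09 ± 0.26 (adjusted p = 0.0204) and lost its call in 5 of 18 other settings (range 0.70 to 1.44). FOLR1 (0.94 ± 0.16, other probe set -0.15) lost its call with the mean of probe sets, and the water channel AQP3 rose by 0.94 ± 0.17 with its other probe sets at -0.25 and 0.44.

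Of the unfolded protein and ATF4 list, 11 of 31 genes fell and 1 rose (18 and 2 when adjusted over the list alone). Its mean was -0.37 (camera adjusted p = 3.0e-10, and adjusted p = 0.0139 with an estimated correlation). MTHFD2 fell by 0.97 ± 0.09 and the serine synthesis enzyme PSAT1 by 0.76 ± 0.10. Of the immediate-early list, 9 of 18 fell (12 when adjusted over the list alone, camera adjusted p = 6.6e-11, and adjusted p = 0.00115 with an estimated correlation). Among them were IER3 (-0.77 ± 0.10), DUSP5 (-0.80 ± 0.13) and FOSL1 (-0.93 ± 0.16). Of the growth factor and matrix list, 8 of 30 fell (12 when adjusted over the list alone, camera adjusted p = 1.7e-07, and adjusted p = 0.0330 with an estimated correlation). Its falls included CCN2 (-1.03 ± 0.19) and TGFB2 (-0.69 ± 0.13, lost with the mean of probe sets). Of the known targets of IL-13, 2 of 7 rose, CISH and TGM2 (0.81 ± 0.10), with 3 when adjusted over the list alone (camera adjusted p = 0.00402, and adjusted p = 0.0453 with an estimated correlation). Its mean was 0.36, beside 0.28 in untreated cells at 24 h against 0 h. Its adjusted p with an estimated correlation ran from 0.0160 to 0.231 over the other settings, and that of the growth factor and matrix list from 0.0149 to 0.0830. The inflammatory list gave 1 rise, C3, and 2 falls, CXCL2 and CXCL1 (-0.74 ± 0.19, call lost in 8 of 18 other settings), among 15 (camera adjusted p = 0.00908, and adjusted p = 0.0855 with an estimated correlation). The circadian list gave 1 fall, BHLHE40 (-0.38 ± 0.10, call lost in 8 of 19 other settings), among 8 (camera adjusted p = 0.0334, and adjusted p = 0.0855 with an estimated correlation), and lost its call with no filter and with the mean of probe sets. The adjusted p of the ATF4 list with an estimated correlation ran from 0.00672 to 0.0964 over the other settings, the highest with median scaling.

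Limma called 285 genes at 12 h, 107 higher and 178 lower (37.5% higher), 19 of them by at least 2-fold (4 higher, 15 lower). With median scaling 47 were higher and 211 lower (18.2%). The count was 133, 135, 152 and 159 without control 0 h array b, IL-13 12 h array c, control 0 h array c and control 0 h array a, and 188 without either IL-13 12 h array a or b. No untreated 12 h arrays set these changes apart from time in culture. IL13RA1 (0.33 ± 0.13, adjusted p = 0.203), MUC5AC (0.09 ± 0.24) and STAT6 (0.03 ± 0.11, and -0.06 with median scaling) did not pass.

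**Figure D2:**
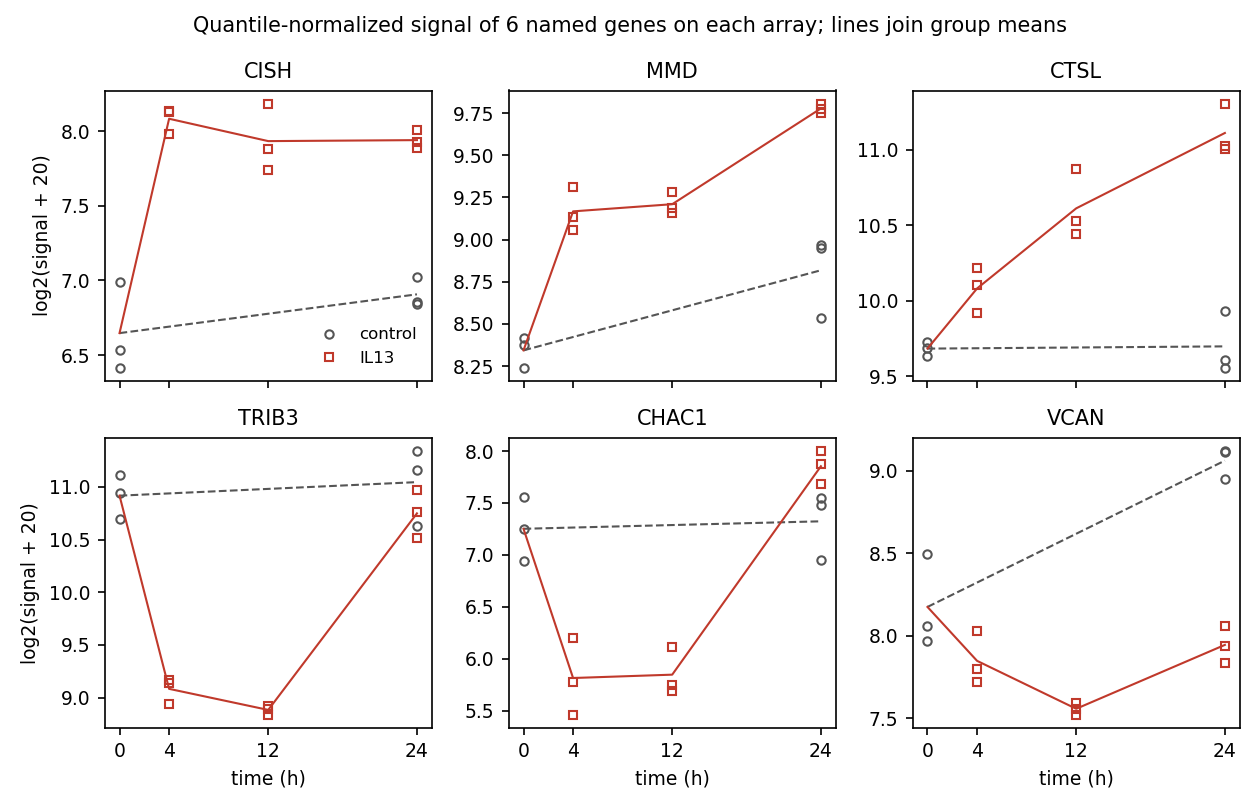
Quantile-normalized log2 signal of 6 named genes on each array against time, with lines joining the means of the untreated groups (grey, dashed) and the IL-13 groups (red). CISH was high from 4 h on, TRIB3 and CHAC1 were low at 4 h and 12 h, and VCAN at 24 h was higher in the untreated cells.

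The genes of the time-matched comparison were followed back to 4 h and 12 h against 0 h, which share no compared arrays with it. Each gene's variance was estimated once over all arrays and used in every comparison, so calls of the same gene are not independent. The counts expected under independence are therefore no valid reference, and nothing is concluded from the excess over them. Of the 271 genes higher at 24 h, 14 were also called higher at 4 h against 0.945 expected if the calls were independent, among them CISH, HK1, MMD, MSX1, TGM2, INSIG1 and TBC1D4. Another 2 were called lower. At 12 h 40 were called higher against 4.21 expected, among them C3, CTSL, MBNL2, ENC1 and OLFML2A, and 4 were called lower. Of the 211 genes lower at 24 h, 5 were also lower at 4 h (BTG1, GRB10, NAV2, PFKFB3 and SOX4; 1.84 expected), of which all but NAV2 were named after their values were seen. At 12 h 26 were also lower against 5.46 expected, VCAN, IRS2, IGFBP3 and EDN1 among them, and 3 were called higher. By sign alone, 52.0% of the genes higher at 24 h stood higher at 4 h, beside 50.9% of all tested genes, and 73.1% at 12 h, beside 51.5%. Of the genes lower at 24 h, 44.1% stood lower at 4 h, beside 49.1% of all tested genes, and 62.1% at 12 h, beside 48.5%.

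Against 0 h, 24 h of IL-13 combined the treatment with a day in culture. C3 rose by 1.81 ± 0.26 (3.51-fold, adjusted p = 0.000300) and MBNL2 by 1.60 ± 0.16. The monocyte-to-macrophage differentiation gene MMD rose by 1.44 ± 0.11 (2.70-fold, adjusted p = 1.0e-06), CTSL by 1.43 ± 0.12, CISH by 1.29 ± 0.14 and TGM2 by 0.80 ± 0.10 (other probe sets -0.53 to 0.90). ARHGDIA fell by 1.62 ± 0.18 (3.08-fold), the cytoskeletal linker PLEC by 1.15 ± 0.25 (call lost without IL-13 24 h array c) and the focal adhesion protein ZYX by 1.05 ± 0.14. The mean deposited signal of ARHGDIA was 258.6 at 0 h and 100.4 in the untreated 24 h control, so it was also lower without IL-13. PTPRO (-1.27 ± 0.22, other probe set 0.19) lost its call with the mean of probe sets. TCIM (1.41 ± 0.36) and CACNA1I (-1.39 ± 0.35, other probe sets -0.11 and 0.16) lost their calls with no filter. Limma called 473 genes, 234 higher and 239 lower, 27 of them by at least 2-fold (21 higher, 6 lower). The count was 210 without IL-13 24 h array c, and 250, 269 and 304 without control 0 h arrays c, b and a.

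In this comparison 9 of 32 mitotic genes fell (12 when adjusted over the list alone, camera adjusted p = 9.3e-08, and adjusted p = 0.200 with an estimated correlation). They included UBE2C (-0.53 ± 0.09), CDC20 (-0.58 ± 0.11) and PTTG1 (-0.59 ± 0.12), which act at the anaphase-promoting complex. Of the DNA replication list 4 of 28 fell (6 when adjusted over the list alone, camera adjusted p = 6.9e-06, and adjusted p = 0.259 with an estimated correlation), including the ribonucleotide reductase subunit RRM2 (-0.65 ± 0.12). Of the growth factor and matrix list 9 of 30 fell and 1 rose (12 and 1 when adjusted over the list alone, camera adjusted p = 2.9e-05, and adjusted p = 0.200 with an estimated correlation). COL4A1 (-0.71 ± 0.14), COL4A2 (-0.70 ± 0.15) and TIMP2 (-0.77 ± 0.15) were among the falls, and COL4A2 lost its call without IL-13 24 h array c. The list of known IL-13 targets passed with 2 rises of 7, CISH and TGM2 (camera adjusted p = 0.0310, and adjusted p = 0.200 with an estimated correlation). The list's score against the 0 h mean was 0.32 ± 0.11 after 24 h of IL-13 and 0.28 ± 0.09 in the untreated 24 h control (mean ± SD, n = 3 arrays). The call was lost with only these groups, with array weights, and without control 0 h array a or c or IL-13 24 h array b. MUC5AC (-0.29 ± 0.24), IL13RA1 (0.20 ± 0.13) and STAT6 (-0.04 ± 0.11) did not pass.

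Between 4 h and 12 h of IL-13 limma called 0 genes, with 697 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0677. The genes with the smallest p were ARHGDIA (-1.07 ± 0.18), the mitotic transcription factor FOXM1 (-0.75 ± 0.14), SMARCC2 (-0.61 ± 0.11), ID1 (0.56 ± 0.10) and CTNNAL1 (-0.41 ± 0.08, adjusted p = 0.111), and CISH stood at -0.15 ± 0.14. The growth factor and matrix list stood lower at 12 h (mean -0.18; camera adjusted p = 9.6e-05, and adjusted p = 0.174 with an estimated correlation), with TGFB1 at -0.53 ± 0.15 (adjusted p = 0.171). The immediate-early list stood lower as well (mean -0.15; camera adjusted p = 0.0282, and adjusted p = 0.174 with an estimated correlation), with FOSL1 at -0.61 ± 0.16 (adjusted p = 0.154). The immediate-early call was lost with the pseudocount at the median, no filter, the filter at the 75th percentile, array weights, and without IL-13 4 h or 12 h array c. With only these groups in the model 4 genes were called, without IL-13 12 h array a 3, and with median scaling or a pseudocount at the median 1.

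The last question was what changed between 12 h and 24 h of IL-13. Some genes of the ATF4 and immediate-early lists rose. Some genes of the mitotic and DNA replication lists fell, as did the heat shock gene HSPA2. CHAC1 rose by 2.01 ± 0.21 (4.02-fold, adjusted p = 1.3e-05), TRIB3 by 1.87 ± 0.15 (3.65-fold, adjusted p = 7.4e-07) and PMAIP1, a proapoptotic BCL2 family gene, by 1.69 ± 0.14. TSC22D3 rose by 1.51 ± 0.12 and IFRD1 by 1.43 ± 0.14. HSPA2 fell by 1.23 ± 0.15 (2.34-fold, adjusted p = 5.9e-05), the HSP70 and HSP90 adaptor STIP1 by 0.96 ± 0.16 and the kinase CAMKK2 by 0.89 ± 0.16. H2AX fell by 0.97 ± 0.11 on its brightest probe set, with others from -0.29 to 0.08 and its call lost with the mean of probe sets. H6PD (-0.92 ± 0.26) lost its call in 7 of 17 other settings (range -1.24 to -0.50).

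Of the unfolded protein and ATF4 list, 16 of 31 genes rose (17 when adjusted over the list alone). Its mean was 0.47 (camera adjusted p = 2.2e-11, and adjusted p = 0.00973 with an estimated correlation). MTHFD2 rose by 1.10 ± 0.09 and DDIT4 by 1.20 ± 0.13. Of the immediate-early list 8 of 18 rose and 1 fell (9 and 1 when adjusted over the list alone, camera adjusted p = 6.9e-06, and adjusted p = 0.00973 with an estimated correlation). ATF3 (0.83 ± 0.13), DUSP1 (0.57 ± 0.11) and CCN1 (0.83 ± 0.17) were among the rises. Of the mitotic list 10 of 32 fell (18 fell and 1 rose when adjusted over the list alone, camera adjusted p = 2.2e-11, and adjusted p = 0.0639 with an estimated correlation). The falls included the kinesin KIF20A (-0.84 ± 0.12) and UBE2C (-0.52 ± 0.09). Of the DNA replication list 6 of 28 fell (10 when adjusted over the list alone, camera adjusted p = 1.0e-08, and adjusted p = 0.117 with an estimated correlation), including RRM2 (-0.71 ± 0.12) and MCM2 (-0.71 ± 0.14). Of the circadian list 2 of 8 rose, NFIL3 (0.78 ± 0.13) and BHLHE40 (0.56 ± 0.10; camera adjusted p = 0.00589, and adjusted p = 0.0639 with an estimated correlation), and the call was lost with the mean of probe sets. With median scaling the ATF4 and immediate-early lists kept the camera call and lost it with an estimated correlation.

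At 24 h the ATF4 list did not pass the test between IL-13 and its time-matched control. Its mean difference was 0.02 with 1 fall among 31 genes (camera adjusted p = 0.946). TRIB3 stood at -0.30 ± 0.15 (adjusted p = 0.243) and CHAC1 at 0.53 ± 0.21 (adjusted p = 0.129). Against the 0 h mean, the list's score was -0.33 ± 0.06 at 4 h and -0.37 ± 0.03 at 12 h of IL-13, and 0.10 ± 0.05 with and 0.08 ± 0.09 without IL-13 at 24 h (mean ± SD, n = 3 arrays). The mitotic score was 0.03 and 0.05 at 4 h and 12 h and -0.25 ± 0.07 at 24 h of IL-13, beside 0.02 ± 0.14 in the 24 h control. Limma called 427 genes between 12 h and 24 h, 285 higher and 142 lower (66.7% higher), 17 of them by at least 2-fold (16 higher, 1 lower). With median scaling 351 were higher and 70 lower (83.4%). The count was 194 and 205 without IL-13 12 h arrays a and c, and 229 and 255 without IL-13 24 h arrays c and a. CISH (0.01 ± 0.14), IL13RA1 (-0.13 ± 0.13), MUC5AC (-0.38 ± 0.24) and STAT6 (-0.08 ± 0.11) did not pass.

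**Figure D3:**
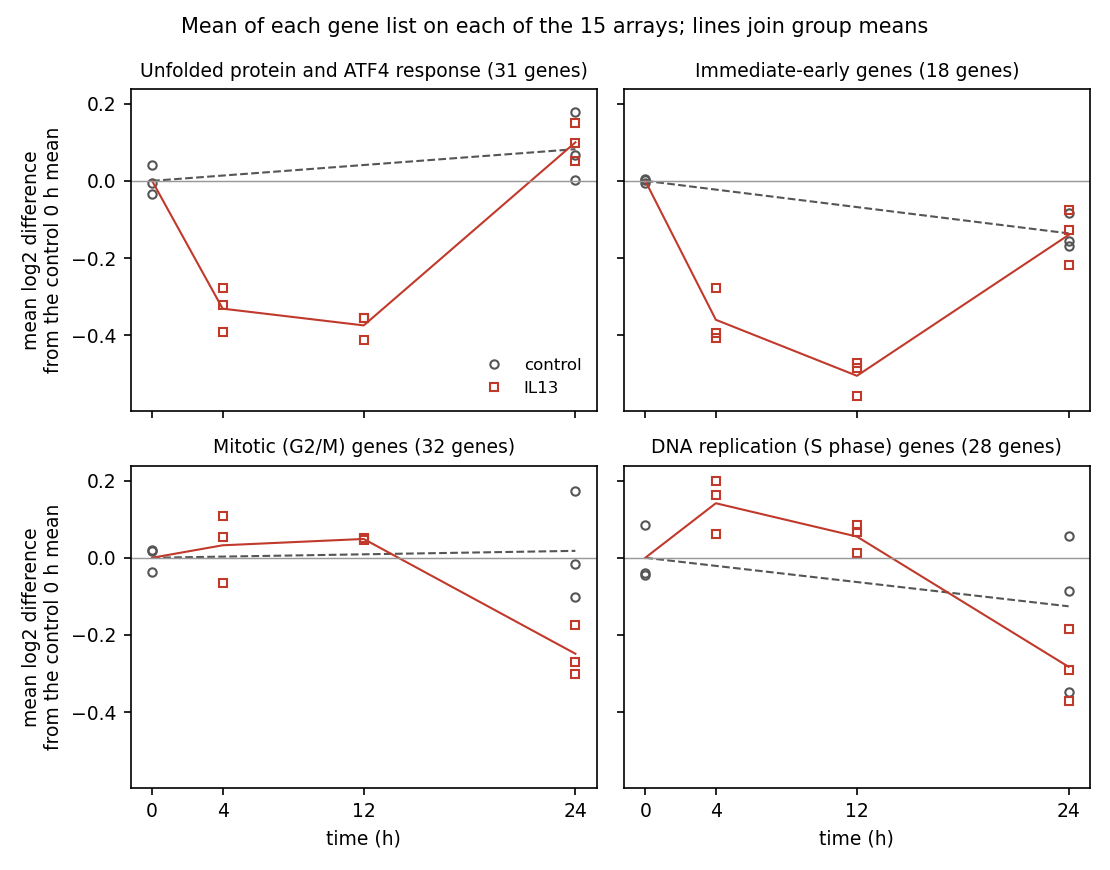
Mean log2 difference from the 0 h control of 4 gene lists on each array, with lines joining group means (grey dashed untreated, red IL-13). The ATF4 and immediate-early lists were low at 4 h and 12 h, where there are no untreated arrays, and the mitotic list was lowest after 24 h of IL-13.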

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

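The tests of array scaling, of a deviating array in the DNA replication list, of a lasting IL-13 effect, of medium and time, of genes varying together and of the hybridisation controls, and the scaling on tested-gene medians, were chosen only after the results were seen.

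Among 1257 bright probe sets with several or no gene symbols, 81 passed the limma threshold at 24 h, 35 higher and 46 lower, in data that no gene name reports on. The change from 0 h differed between 12 h and 24 h of IL-13 for 13 of 27 genes compared by limma. The 27 were chosen for large changes at 12 h or 24 h, which favours such differences, and the test is the same as that of 24 h against 12 h of IL-13 in the report. The change was larger upward at 24 h for CTSL (0.50), MMD (0.57) and MBNL2 (0.88). For CHAC1 (2.01) it went from -1.40 at 12 h to 0.60 at 24 h, where the difference from 0 h did not pass. The change was less negative for TRIB3 (1.87), CXCL2 (0.82), CCN1 (0.83), EREG (0.86) and NPIPA1 (0.99). It was smaller upward for FOLR1 (-0.62) and INSIG1 (-0.55) and more negative for ZYX (-0.48). For HSPA2 (-1.23) it went from 0.94 at 12 h to -0.29 at 24 h, where the difference from 0 h did not pass (limma adjusted p = 0.267).

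The ATF4 and unfolded protein genes were low at 4 h and 12 h of IL-13 and not at 24 h. Array scaling is argued against: over 4 scalings the list's mean at 4 h and 12 h against 0 h was at highest -0.314 (SE 0.0616 over the arrays, 4 h with tested-gene median scaling). A lasting IL-13 effect of -0.187 or lower on the list's mean, midway between 0 and the 12 h value of -0.375, is argued against too. At 24 h the list's mean was 0.0177 against its time-matched control, more than 2 standard errors of 0.0587 above -0.187. A smaller lasting effect is not excluded, because the 12 h value holds both IL-13 and time in culture. A change of medium, feeding or time in culture stays open, because 0 untreated arrays at 4 h and 12 h are labelled. A short-lived IL-13 effect and an effect of handling the cultures cannot be told apart here.

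The mean of the mitotic and of the DNA replication list was lower after 24 h of IL-13 than in the 24 h control, with 7 of 32 and 5 of 28 genes past the threshold. For the mitotic list a single deviating array is argued against: with each of the 6 arrays left out in turn the mean ran from -0.327 to -0.190 (without control 24 h array b), with standard errors of 0.0584 to 0.143. For the DNA replication list a single deviating array stays open: its mean was -0.157, -0.0655 (SE 0.141) without control 24 h array b and -0.268 (SE 0.0896) without control 24 h array c. Array scaling stays open for both lists: with median scaling the mitotic mean was -0.074 (SE 0.131) and the replication mean 0.0028 (SE 0.159). Median scaling took the median difference of all tested genes to 0.138, so these means decide nothing about the lists relative to other genes. Relative to other genes, the mitotic list kept its camera call with median scaling and the replication list did not. A chance fluctuation of genes that vary together stays open, with an adjusted p of 0.372 for the mitotic list when the correlation was estimated (0.0262 unadjusted) and 0.701 for the replication list.

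The share of higher genes at 24 h rose from 56.2% to 93.5% with median scaling. Dim probe sets with a different signal between arrays do not account for it alone, since median scaling on the tested genes still gave 75.1% higher. Less labelled RNA on the control 24 h arrays relative to the spiked-in controls stays open: the 9 hybridisation control probe sets were 0.308 log2 higher there than after 24 h of IL-13 (SD 0.0863 in the latter), but the arrays overlapped, with a lowest value of 9.58 and a highest of 9.60.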

How the results depend on the processing

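Scaling on tested-gene medians was added after the results were seen; the other settings were not. Of gene results over all settings, 3896 kept direction and side of the threshold, 269 lost their call, 25 gained one and 22 turned sign. The gene results that turned sign were preset genes that did not pass, and the cause was not tested. Of list results 526 kept theirs and 65 lost the call. These pool unlike settings: with an estimated correlation alone, 8 list calls were kept and 22 lost. IL13RA1 in control 24 h against 0 h was -0.1299 with median scaling, -0.0704 with the mean of probe sets, and -0.0751 (without control 24 h array a) to 0.1655 (c) with 1 array left out. IL13RA1 in IL13 4 h against control 0 h was 0.0059 without control 0 h array c, 0.0012 without IL-13 4 h array a and -0.0631 without IL-13 4 h array b. MUC5AC in IL13 4 h against control 0 h was 0.0944 and -0.2255 without control 0 h arrays c and a and 0.0797 without IL-13 4 h array b. At 12 h against 0 h it was -0.0041 with array weights, -0.0451 without control 0 h array a, and -0.2051 and 0.2978 without IL-13 12 h arrays c and b; at 12 h against 4 h -0.1176 and 0.3853 without IL-13 12 h arrays c and b. STAT6 with the mean of probe sets was -0.3441 at 4 h and -0.228 at 12 h against 0 h, 0.1161 at 12 h against 4 h and 0.0872 at 24 h against 12 h. At 12 h against 0 h it was also -2e-04 as deposited, -0.0593 with median scaling, -0.0118 without control 0 h array b, and -0.0314 and 0.1032 without IL-13 12 h arrays c and a. CISH at 24 h against 12 h was -0.0206, -0.0915 and 0.1319 without IL-13 12 h arrays a, b and c and -0.0268 without IL-13 24 h array b.

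Counts moved over 1.5 times as follows. IL-13 24 h against control 24 h (482): 1018 with median scaling and 243 with only these groups, causes not tested. With 1 array left out the count ran from 194 (without IL-13 24 h array c) to 539 (without control 24 h array b). Control 24 h against 0 h (249): 877 with median scaling and 155 with no filter, which tests more genes, causes not tested. It was 479 with every probe set, which counts probe sets, and 66 (without control 24 h array c) to 227 with 1 array left out. IL-13 4 h against 0 h (84): 35 (without control 0 h array b) to 74. IL-13 12 h against 0 h (285): 440 with every probe set, and 133 (without control 0 h array b) to 188. IL-13 24 h against 0 h (473): 210 (without IL-13 24 h array c) to 355. IL-13 12 h against 4 h (0): 1 with median scaling, 1 with the pseudocount at the median, 4 with only these groups, and 0 to 3 (without IL-13 12 h array a); the cause was not tested. IL-13 24 h against 12 h (427): 194 (without IL-13 12 h array a) to 369. The replicate letter as a block gave, in this order of comparisons, 390, 194, 60, 235, 379, 0 and 360. Residuals of the 30 same-letter pairs correlated at -0.0220 on average, so no pairing by letter was seen. The mean of the 60 others (0.0111) is tied to that value, because residuals sum to 0 within a group. Whether the letters mark shared cultures or runs stays open. Settings in which a gene was not tested give no value. Signal over background limits what can be called: genes under a mean log2 signal of 6.33, such as IL13RA2, IL4R and SOCS1, were outside the main test.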

Other observations

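The MHC class I and heat shock tests in this part use lists and genes that were chosen only after the values were seen.

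Interferon-stimulated genes gave 2 rises among 12 tested after 24 h of IL-13 against the 24 h control. Of these the immunoproteasome subunit PSMB9 rose by 0.93 ± 0.10 (adjusted p = 5.1e-05), while the list did not pass (mean 0.17, camera adjusted p = 0.128). In untreated cells PSMB9 was lower at 24 h than at 0 h (-0.44 ± 0.10, limma adjusted p = 0.0264). After 24 h of IL-13 it stood 0.49 ± 0.10 higher than at 0 h (limma adjusted p = 0.00844). B2M, the light chain of MHC class I, rose by 0.76 ± 0.09 (adjusted p = 5.7e-05). Other genes picked after their values were seen were the sulfate transporter SLC26A2, which rose by 1.004 ± 0.101 (adjusted p = 2.0e-05) and was also higher at 4 h (0.57 ± 0.10) and 12 h (0.79 ± 0.10) against 0 h, and the mucin glycosyltransferase GCNT3, which rose by 1.03 ± 0.14 (adjusted p = 0.000264) and stood 0.59 ± 0.14 higher at 12 h. The NRF2 and xenobiotic list gave 1 rise and 4 falls among 25 genes at 24 h (camera adjusted p = 0.104), and the p53 target list 1 rise among 15 (camera adjusted p = 0.429).

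A hypothesis from B2M and PSMB9 was that MHC class I presentation genes rose with IL-13. In the 11 other genes of such a list the mean was 0.12 with 1 rise, PSMB10 (0.80 ± 0.16), and camera did not pass (adjusted p = 0.360). Against 0 h the 11 stood higher at 4 h, 12 h and 24 h of IL-13 (camera adjusted p = 0.0292, 0.0166 and 0.0434). None of these held with an estimated correlation (camera adjusted p = 0.190, 0.101 and 0.227). In untreated cells at 24 h against 0 h camera did not pass (adjusted p = 0.456). The hypothesis stays open.

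A second hypothesis came from HSPA2 (-1.23), DNAJA1 (-0.78), DNAJB1 (-0.71), HSP90AB1 (-0.59) and STIP1 (-0.96), all lower at 24 h than at 12 h of IL-13: heat shock chaperone genes may fall between these times. The 11 other genes of such a list had a mean of -0.26 with 2 falls, BAG3 (-0.72) and HSPE1 (-0.64), and camera passed (adjusted p = 0.000217), though not with an estimated correlation (adjusted p = 0.141). IL-13 and time are not separated in it. In IL-13 24 h against control 24 h the 11 other genes had a mean of 0.08. Of the genes that prompted the hypothesis, only HSP90AB1 passed there (-0.31, limma adjusted p = 0.0334). At 12 h against 0 h the 11 had stood higher, with a mean of 0.29 (camera adjusted p = 8.1e-06, and adjusted p = 0.0732 with an estimated correlation).

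The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.1. A mixed split puts any difference between the groups into the residual spread, which lowers its count. Low counts in the other splits therefore say nothing about the cause of a difference. The real split was the 1 with as many genes for IL-13 24 h against control 24 h (482, highest other 0), control 24 h against 0 h (249, highest other 0), 4 h against 0 h (84, highest other 0), 12 h against 0 h (285, highest other 0), 24 h against 0 h (473, highest other 0) and 24 h against 12 h (427, highest other 0); for 12 h against 4 h (0) all 10 gave as many, the highest other being 3.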
